A study of Mus musculus with 12 samples.

How the data were processed

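Total RNA from 4 isolated mouse germ cell types was labelled by the Affymetrix one-cycle method and hybridised to the 3 Affymetrix array designs U74Av2, U74Bv2 and U74Cv2, per the labels. The labels describe each of the 12 arrays as a single sample, give 1 array per cell type and design, and state neither the isolation method nor the age of the mice. The values the authors deposited are intensity signals per probe set on a linear scale, made with MAS5 per the submitters' processing notes, with version and settings not given in the sources used here. The values show that each array had been scaled to a 2% trimmed mean between 125.0 and 125.1. Detection calls were not used here.

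From these signals, each array was scaled to the geometric mean, over the 4 arrays of its design, of their 2% trimmed means, which altered the deposited values little. A floor was set at 0.4 of that mean, between 50.01 and 50.03 units, values below were set to it, and log2 was taken. A ratio in which the lower cell type is at the floor is a lower bound, and no fold is given where both are. Control probe sets stayed out of gene results. Of 228 readings of negative controls (bacterial and yeast sequences, 19 per array) 22 exceeded the floor and the highest read 103.5. Levels just over the floor are not told from background. The depth of an array is its signal over this background.

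Probe sets were named through the platform annotation given with the arrays: of 36701 non-control probe sets 29131 had 1 gene symbol, 724 several and 6846 none. Symbols were updated through the Entrez gene identifier to a RefSeq table of assembly GRCm38.p6, in which 29044 matched, and the same table gave chromosomes and no coordinates. A gene was represented by the probe set with the highest mean signal over the 4 cell types. Designs were scaled separately by the authors, and the same control probe sets read 1.96-fold higher on U74Bv2 and 3.16-fold higher on U74Cv2 than on U74Av2, which enters the choice between probe sets on different designs; ratios are always within a design.

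The 3 steps between neighbours among the sampled cell types were compared: type B over type A spermatogonia, pachytene spermatocytes over type B spermatogonia, and round spermatids over pachytene spermatocytes. Stages between the sampled cell types were not measured. With 1 array per cell type and design no test was run. Genes differing by at least 4-fold were counted, as were genes at least 4-fold over each of the other 3 cell types. Medians of 27 gene lists were set against 10000 random lists of the same size matched on mean level in 10 bins. A list was said to stand apart below percentile 1 or above percentile 99, which 29 of the 81 combinations of list and step did. Lists of randomly drawn genes would give 1.62 on average. Genes of a list may vary together, some lists share genes and the steps share arrays, so setting 29 against 1.62 is no test. Members of a list that differed by at least 2-fold were counted. The lists, the thresholds, the rule for named genes and all alternatives but the 2 named last below were fixed before the data were examined. The lists covered undifferentiated and differentiating spermatogonia, replication, mitosis, recombination and synapsis, pachytene expression, piRNA pathway, acrosome, sperm tail, sperm chromatin, germ cell and general isoforms of metabolic enzymes, X-linked parents and their retrogenes, ribosome, proteasome, respiratory chain, sterol synthesis, immediate early response, imprinting, and Sertoli, Leydig, myoid, fibroblast, leukocyte, erythroid and endothelial cells; 18 genes were in more than 1 list. X-linked genes were treated in the same way.

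The rule named, for each step, the 8 genes with the largest ratio in each direction among those over the floor in both cell types and at least 2 floors in the higher, and the 5 in each direction with the highest lower bound. It further named the 5 genes with the largest ratio over the next cell type for each cell type, up to 4 members of a list at the steps where it is described, and all members of the retrogene lists. X-linked genes were named as members of a list are, and all 4 measured Y-linked genes by their values. Gfra1, Peg3, Tsga8 at pachytene, the genes low in pachytene spermatocytes alone and the genes whose signals are given were chosen after their values were seen. A gene whose probe sets differed by over 2-fold in opposite directions is named with that said.

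The technical spread was the SD of the log2 ratio of the same control probe set over the 3 designs, and the share of probe set pairs of a gene that differed in ratio. Intervals are 95% bootstrap intervals from 2000 draws of genes. They give a spread over genes and no error between cell preparations. On simulated data with noise of the control probe sets and 200 planted genes, 41.8% of genes with a planted 4-fold change and 91.0% with an 8-fold change were called for type B over type A (11566 genes). The shares were 37.3% and 82.1% for pachytene over type B (11564 genes), and 37.3% and 86.6% for round spermatids over pachytene (11042 genes), and 0 unchanged genes were called. Noise of the control probe sets is small against a 4-fold threshold, so this 0 was nearly fixed beforehand and does not test false calls. Probe sets of the same gene over the floor in both cell types spread more. The pooled SD of their log2 ratio was 0.50, 0.83 and 0.75 at these steps. That larger spread was not simulated, and the shares hold only for the noise used. Lists without a planted shift stood apart in 1.5%, 1.5% and 3% of 200 draws at these steps, with 1000 random lists each. They were drawn from the same genes as the random lists, so the percentile limits nearly fixed these shares. False calls for lists of genes that vary together were thus not tested. A planted 4-fold change lies on the 4-fold threshold, so the shares called for it were also largely set by construction. Biological variation was not simulated.

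Alternatives were: signals as deposited, quantile normalization, a common median, floors of 0.2 and 0.8 of the trimmed mean or none, the mean over a gene's probe sets, leaving out probe sets with special endings, U74Av2 only, thresholds of 2-fold and 8-fold, each probe set on its own, and random lists not matched on level. Scaling to the bacterial spike-in controls and choosing the probe set after the designs were put on a common scale were added after seeing the data. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.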

Results

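RNA of 4 isolated mouse germ cell types, type A spermatogonia, type B spermatogonia, pachytene spermatocytes and round spermatids, was hybridised to 3 Affymetrix designs (U74Av2, U74Bv2 and U74Cv2) that carry partly different genes. The 12 arrays comprised 1 array per cell type and design, so no difference between cell types has a replicate error or a p-value, and the number of arrays limits the precision. After scaling, the array medians lay between 42.7 and 75.9 signal units, and 54.7% of probe sets in type A spermatogonia, 56.7% in type B spermatogonia, 47.8% in pachytene spermatocytes and 47.6% in round spermatids exceeded a floor, which lay between 50.01 and 50.03 on the 3 designs. The arrays gave a level over the floor in at least 1 cell type for 13003 of 15964 named genes. A ratio against a cell type at the floor is a lower bound relative to that floor and is written as at least so many fold. Negative controls read up to 103.5 on the type B U74Cv2 array, so a ratio whose lower signal lies under the highest negative control of its array is not firm, even where both signals exceed the floor.

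Across these 13003 genes the type A and type B spermatogonia were the most alike of the 6 pairs, with a Spearman's rho of 0.900, followed by pachytene spermatocytes and round spermatids with 0.789. Type A spermatogonia and pachytene spermatocytes had a rho of 0.561, type B spermatogonia and pachytene spermatocytes 0.551, type B spermatogonia and round spermatids 0.449, and type A spermatogonia and round spermatids 0.428. These values are across genes, which are not independent replicates. The technical spread was read from repeats within the arrays. The log2 ratio of the same control probe set over the 3 designs had an SD of 0.23 for type B over type A, 0.22 for pachytene over type B and 0.40 for round spermatids over pachytene. Pairs of probe sets of the same gene differed in their ratio by more than 2-fold in 15.2%, 32.4% and 27.7% of pairs at these 3 steps.

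The first comparison, of type B with type A spermatogonia, addressed the difference between 2 mitotic stages of spermatogonia. In type B spermatogonia 20 genes were at least 4-fold higher and 21 at least 4-fold lower. Under spike-in scaling these counts were 1 and 172, and how the spike-in controls were added is not given in the sources used here. Among genes measured in both, Ttc16 was 5.09-fold, Gm10125 4.90-fold, Itm2a 4.65-fold, Krt6a, a keratin, 4.54-fold, Sh2d3c 4.48-fold, the splicing regulator Rbfox2 4.34-fold, Spindoc 4.13-fold and C1qtnf6 4.12-fold higher. Sgip1 was at least 11.5-fold, the homeobox gene Meis1 at least 6.26-fold, the orphan receptor Gpr75 at least 5.04-fold, the lysozyme gene Lyz1 at least 4.74-fold and 1110032A03Rik at least 4.68-fold higher. Stat2, a transcription factor of interferon signalling, was 11.6-fold, Irf2bpl 10-fold, Pdlim7 9.37-fold, Cwf19l2 7.53-fold, Agps, an enzyme of ether lipid synthesis, 5.11-fold, Rbm28 5.09-fold, Decr2, a peroxisomal reductase, 4.85-fold and Cit, the citron kinase of cytokinesis, 4.74-fold lower. Ankrd61 was at least 6.96-fold, the potassium channel gene Kcnma1 at least 5.71-fold, Dnajc18 at least 4.34-fold, the small GTPase gene Rab27b at least 4.27-fold and Rflna at least 4.20-fold lower. Of the 4-fold differences measured in both, the lower signal lay under the highest negative control of its array for 3 of 10 higher genes, among them Sh2d3c and C1qtnf6, and for 9 of 14 lower genes, among them Stat2, Irf2bpl, Pdlim7, Cwf19l2, Agps and Decr2. The order and size of these ratios therefore depend on background.

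In the list of undifferentiated spermatogonia, 3 of 20 measured members were at least 2-fold higher in type B and 2 lower: Utf1 at least 3.16-fold, Epcam 2.66-fold and Sall4 2.61-fold higher, the last with probe sets that disagreed in sign, and Zbtb16 2.50-fold and Gfra1 2.20-fold lower. The lower signal of Gfra1 lay under the highest negative control. Epcam came under 2-fold in 2 of 10 alternative settings, down to a log2 of 0.28. Zbtb16 encodes a transcription factor of spermatogonial stem cells and Gfra1 the receptor subunit for the growth factor GDNF. The list median was -0.10 on the log2 scale, at percentile 11.4 of 10000 random lists of the same size matched on level. Among the 19 measured members of the differentiating list, Rbm44 was 2.30-fold lower and none was 2-fold higher; the receptor gene Kit was 1.91-fold and Dmrt1 1.81-fold lower, and the median was -0.26 at percentile 3.09. The mitosis list had a median of -0.23 at percentile 1.86, with Cenpf 3.53-fold and Aurkb 2.45-fold lower among 35 members. The replication list had a median of -0.01 at percentile 25.1, with Chaf1b 3.03-fold and Mcm6, from a signal under the highest negative control, 2.28-fold higher among 45. Each of these 4 lists stayed within the percentiles 1 to 99 set for standing apart, but the mitosis list passed them in 3 and the differentiating list in 1 of 12 alternative settings. Under spike-in scaling the medians were -0.89 for the undifferentiated, -1.09 for the differentiating, -1.05 for the mitosis and -0.84 for the replication list.

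Lists that stood apart in type B against type A spermatogonia held genes of other testis cells and of general cell functions, and each of their medians turned negative or came to 0.00 when the arrays were scaled to the bacterial spike-in controls. Among 20 fibroblast and matrix genes 7 were at least 2-fold higher and none lower in type B, with a median log2 of 0.71 that turned to -0.11 under spike-in scaling; Lum was 3.69-fold, Dcn 3.17-fold, Bgn 2.77-fold and Postn at least 2.69-fold higher. Among 14 Leydig cell genes 4 were at least 2-fold higher and none lower, with a median of 0.73 that turned to -0.02; Sult1e1, from a signal under the highest negative control, was 2.81-fold and Agt at least 2.77-fold higher. Peritubular myoid genes had a median of 0.49 that turned to -0.37, with Tagln 2.32-fold higher and 2 of 12 members at least 2-fold higher. Macrophage and leukocyte genes had a median of 0.56 that came to 0.00, with C1qa 2.04-fold higher and 2 of 15 members at least 2-fold higher. Ribosomal protein genes had a median of 0.39 that turned to -0.41, immediate early genes 0.47 that turned to -0.35, imprinted genes 0.43 that turned to -0.25, proteasome genes 0.26 that turned to -0.56 and respiratory chain genes 0.20 that turned to -0.59. Of these, 3 of 27 ribosomal, 1 of 22 immediate early, 2 of 16 imprinted, 0 of 31 proteasome and 1 of 40 respiratory chain genes were at least 2-fold higher, and 1 ribosomal protein gene was at least 2-fold lower.

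In the opposite sense, Sertoli cell genes had a median log2 of -0.24 in type B over type A, at percentile 1.65, which did not stand apart in any of the 12 alternative settings either, with Inhbb 2.50-fold and Wt1 2.31-fold lower. The spike-in controls themselves read 1.76-fold higher on the type B arrays, and scaling to them moved the median of all genes by -0.69. Relative to level-matched random lists under that scaling, the fibroblast list remained higher by 0.61 and the Leydig list by 0.59. The ribosomal, proteasome and immediate early lists also stood apart there, whereas the myoid, macrophage, respiratory chain and imprinted lists did not. Over the 12 alternative settings the myoid list stood apart in 8, the imprinted list in 9, the respiratory chain list in 10, and the macrophage and ribosomal lists in 11. Other probe sets of the same gene differed by at least 2-fold in the same direction in 1 of 8 higher and 0 of 10 lower genes that had them. The direction of Gfra1, Kcnma1, Pdlim7, Sall4, Sh2d3c and Utf1 turned when another probe set of the gene was taken. Without probe sets of special endings, Rbfox2, Spindoc, Stat2, Irf2bpl, Cwf19l2, Rbm28, Zbtb16, Aurkb, Mcm6 and Bgn came under 2-fold, with a log2 ratio of 0.00 for Rbm28.

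The second comparison, of pachytene spermatocytes with type B spermatogonia, spanned the entry into meiosis and showed the largest difference among the 3 steps: 970 genes were at least 4-fold higher in pachytene spermatocytes and 668 at least 4-fold lower. The split moved with the scaling, to 1420 higher and 339 lower under a common median and to 1543 and 242 under spike-in scaling. More genes were lower than higher with no floor (1234 higher and 1478 lower), at a 2-fold threshold (2105 and 2854) and on U74Av2 only (331 and 347). The list of genes known to be expressed in pachytene had 21 of 28 measured members at least 2-fold higher and 2 lower, with a median log2 of 3.33 at percentile 100 of random lists. The germ cell lactate dehydrogenase gene Ldhc was at least 174-fold, Tdrd6, a tudor protein of the chromatoid body, 148-fold, the RNA-binding protein gene Ybx2 at least 76.5-fold and Crisp2 at least 73.3-fold higher. In the piRNA pathway 9 of 13 genes were at least 2-fold higher and none lower, with a median of 2.63; the helicase gene Ddx25 was 25.6-fold, Tdrd7 9.70-fold and Rnf17 at least 9.70-fold higher.

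Genes of later sperm structures also read higher on the pachytene than on the type B arrays. The isolation method is not given, and whether RNA of later germ cells enters these signals was not tested. Of 34 sperm tail and axoneme genes 27 were at least 2-fold higher and none lower, with a median log2 of 3.05. The channel gene Catsper2 was at least 67.7-fold, the dynein genes Dnali1 and Dnah8 at least 59.9-fold and at least 44.5-fold, and Ropn1l at least 54.5-fold higher. Of 26 acrosome genes 15 were at least 2-fold higher and none lower, with a median of 1.40; Zpbp2, of the zona pellucida binding proteins, was 132-fold, Adam5 at least 70.6-fold and the protease gene Acr at least 37.5-fold higher. Of 19 sperm chromatin and spermatid transcription genes 11 were at least 2-fold higher and none lower, with a median of 1.55. In this list Gtf2a1l was at least 129-fold, the bromodomain gene Brdt at least 65.9-fold, the protamine gene Prm1 at least 26.4-fold and the transcription factor gene Rfx2 at least 19.003-fold higher. Each of these 3 lists lay over percentile 99 in all 12 alternative settings.

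**Figure D1:**
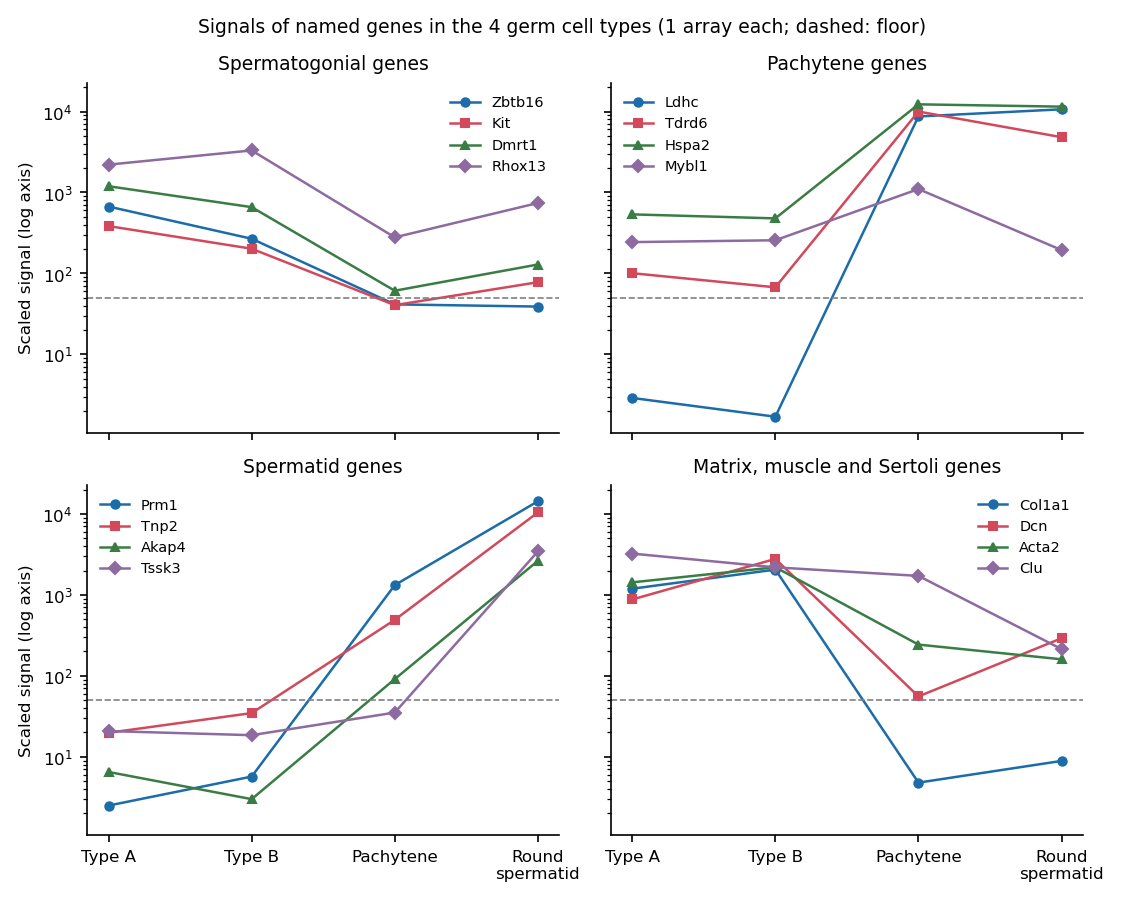
Scaled array signal (log axis) of 16 genes in the 4 germ cell types, 1 array per point, with the floor as a dashed line. The plotted spermatogonial, matrix and muscle genes were lower in pachytene spermatocytes than in type B spermatogonia. Ldhc was at least 174-fold higher in pachytene spermatocytes, and Akap4 was 28.9-fold higher in round spermatids than there.

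Genes of energy metabolism differed by list between type B spermatogonia and pachytene spermatocytes. Fibroblast, myoid and Sertoli markers were lower at this step too, with medians of -2.80, -2.03 and -0.90. The Leydig, macrophage, erythroid and endothelial lists did not stand apart. Whether loss of RNA of other cells enters the metabolic differences was not tested. Of 16 genes in the germ cell metabolic list 10 were at least 2-fold higher in pachytene and 2 lower. The median log2 was 3.13. Ldhal6b was at least 307-fold, the glucose transporter gene Slc2a3 76.6-fold and Cox8c 73.99-fold higher. The list also holds genes that are not particular to germ cells, such as Slc2a3. Of 16 broadly expressed isoforms 8 were at least 2-fold lower and 2 higher, with a median of -1.18 that passed the percentile limit in 11 of 12 alternative settings; Pgam1 was 4.35-fold and Slc25a4 4.14-fold lower, whereas Ldha was 10.2-fold and Pfkp at least 6.13-fold higher. Autosomal retrogenes of X-linked parents had a median of 2.20, with 5 of 8 at least 2-fold higher. Cetn1 was at least 36.8-fold, Pdha2 28.9-fold, Rpl10l 10.1-fold, Pgk2 at least 6.66-fold and Cstf2t 3.16-fold higher, the last with probe sets that disagreed in sign. Gk2 was 1.99-fold higher, from a signal under the highest negative control, and Rbmxl2 and G6pd2 were at the floor in both cell types. Of their 7 measured X-linked parents 3 were at least 2-fold lower and none higher: Cstf2 at least 5.05-fold, Pdha1 at least 4.05-fold and Pgk1 at least 3.16-fold. Zfx was at least 1.66-fold, Cetn2 at least 1.45-fold, Rbmx 1.16-fold and Utp14a at least 1.002-fold lower. The direction of Rbmx turned in 2 of 11 alternative settings, to a log2 of up to 0.55. The parents' median of -0.73 did not stand apart, at percentile 22.9, but with no floor it was -2.57 and stood apart. With the mean over probe sets Cstf2 and Cstf2t came under 2-fold.

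Against matched random lists, genes of differentiating spermatogonia were lower as a list in pachytene spermatocytes. The list of undifferentiated spermatogonia did not stand apart. Of 19 genes of differentiating spermatogonia 12 were at least 2-fold lower and 3 higher, with a median log2 of -1.90 at percentile 0 in the matched lists. Among them Rhox13 was 11.8-fold, Dmrt1, a transcription factor of the mitosis to meiosis switch, 10.8-fold and the deubiquitinase gene Usp26 10.1-fold lower, and Dmrtb1 was 11.4-fold higher. The bootstrap interval of this list's median over genes ran from -2.79 to 0.17 and so held 0. That of the undifferentiated list ran from -1.66 to -0.18. Of the 19 differentiating genes 4, Rhox13 among them, are X-linked, with a median of -2.75. Of 20 genes of undifferentiated spermatogonia 9 were at least 2-fold lower and 1 higher, with Mcam 6.75-fold, Sall4 6.68-fold, Zbtb16 at least 5.36-fold and Taf4b at least 4.09-fold lower; the median of -0.79 lay at percentile 4.68, passed the limit in 1 of 12 alternative settings and came to -0.03 under spike-in scaling. Of 45 replication genes 15 were at least 2-fold lower and 4 higher, with the helicase genes Mcm2 8.08-fold and Mcm4 5.41-fold and the polymerase gene Pold1 6.23-fold lower and Rpa1 5.07-fold higher (Pold1 came to a log2 of -0.58 under spike-in scaling); the median of -0.58 lay at percentile 2.78, passed the limit in 3 of 12 alternative settings and came to 0.00 under spike-in scaling. The mitosis list had a median of 0.00, or 0.98 under spike-in scaling, with the kinase genes Aurka 8.47-fold and Nek2 7.81-fold and Cks2 5.03-fold higher and Cks1b 6.46-fold lower. The list of recombination and synapsis genes did not stand apart, with a median of 0.21 at percentile 96.5 that turned to -0.23 on U74Av2 only. Of its 30 members 10 were at least 2-fold higher and 5 lower, among them Meig1 at least 20.4-fold, Psmc3ip 10.1-fold and Spo11, the nuclease of meiotic double-strand breaks, 6.05-fold higher, and Syce2, of the synaptonemal complex, 5.09-fold lower.

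Genes of matrix, muscle, stress response and ribosome were also lower in pachytene spermatocytes than in type B spermatogonia. Of 20 fibroblast and matrix genes 17 were at least 2-fold lower and none higher, with a median log2 of -2.80. In this list Dcn, the proteoglycan decorin, was 49.96-fold, Bgn at least 47.2-fold, and the collagen genes Col1a2 at least 47.0-fold, Col1a1 at least 41.1-fold and Col3a1 at least 31.4-fold lower. Of 12 myoid genes 9 were at least 2-fold lower, with a median of -2.03; Myh11 was 12.5-fold, Tpm1 9.37-fold and Acta2 9.03-fold lower. Of 25 Sertoli cell genes 10 were at least 2-fold lower and 1 higher, with a median of -0.90 that passed the percentile limit in 8 of 12 alternative settings; Gata4 was 5.46-fold and Wnt6 5.35-fold lower, the latter under 2-fold without probe sets of special endings. Of 22 immediate early and stress genes 21 were at least 2-fold lower and 1 higher, with a median of -2.88. Gadd45b was 15.8-fold, Nr4a1 15.6-fold, Egr1 14.9-fold and Fos 10.4-fold lower. These genes were listed as induced within minutes to hours by tissue dissociation or stress. The isolation method is not given, so a difference in handling of the cells cannot be told apart from a difference between cell types. Of 27 ribosomal protein genes 15 were at least 2-fold lower and none higher, with a median of -1.16 that came to -0.40 under spike-in scaling; Rps19 was 9.59-fold and Rpl10a 5.17-fold lower. Markers of these other cell types were abundant on the spermatogonial arrays. The signal of Col1a1 was 1192 in type A, 2054 in type B and under the floor in pachytene. That of Clu, a Sertoli cell marker, was 3237 in type A, 2189.5 in type B and 1717 in pachytene. The direction of Clu from type B to pachytene turned in 2 of 11 alternative settings, to a log2 of up to 0.42. The Leydig, macrophage, erythroid and endothelial lists did not stand apart, with medians of -0.27, -0.67, -0.21 and -0.76, of which the Leydig median turned to 0.22 and the erythroid median to 0.17 under spike-in scaling. The macrophage list, at percentile 1.28, stood apart in 8 of 12 alternative settings and the endothelial list in 1.

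The largest single ratios in pachytene spermatocytes over type B spermatogonia among genes measured in both belonged to Rbakdn at 189-fold, Tdrd6 and Zpbp2 as above, Stpg4 at 117-fold, Plaat5 at 114-fold, the ubiquitin-conjugating enzyme gene Ube2d2b at 98.2-fold, the asparaginase gene Asrgl1 at 97.8-fold and Ms4a19 at 94.3-fold. The type B signals of Tdrd6, Stpg4, Plaat5, Ube2d2b, Asrgl1 and Ms4a19 lay under the highest negative control of that array, so the size and order of these ratios depend on background, as for 102 of 617 genes at least 4-fold higher and 11 of 377 lower that were measured in both. From the floor, Pebp4 was at least 323-fold, 1700108J01Rik at least 215-fold, Prps1l1 at least 199-fold, a difference that was not seen without probe sets of special endings, and 4930544G11Rik at least 197-fold higher. Besides Dcn, the lower genes were led by Col4a4 at 29.5-fold, Slit3 at 23.9-fold, the imprinted genes Plagl1 at 19.6-fold and Dlk1 at 18.1-fold, Igfbp6 at 17.5-fold, Cnn3 at 17.4-fold and Grasp at 17.4-fold, and Prss35 was at least 75.5-fold lower. The log2 ratio of Plagl1 came to -0.69 without probe sets of special endings and on U74Av2 only. The median of all genes at this step was -0.21, and it moved by 0.31 under a common median, by 0.17 under quantile normalization and by 0.42 under spike-in scaling, so percentiles among random lists compare a list with other genes of the same arrays. Of the genes with other probe sets, these differed by at least 2-fold in the same direction in 183 of 397 higher and 101 of 282 lower genes.

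**Figure D2:**
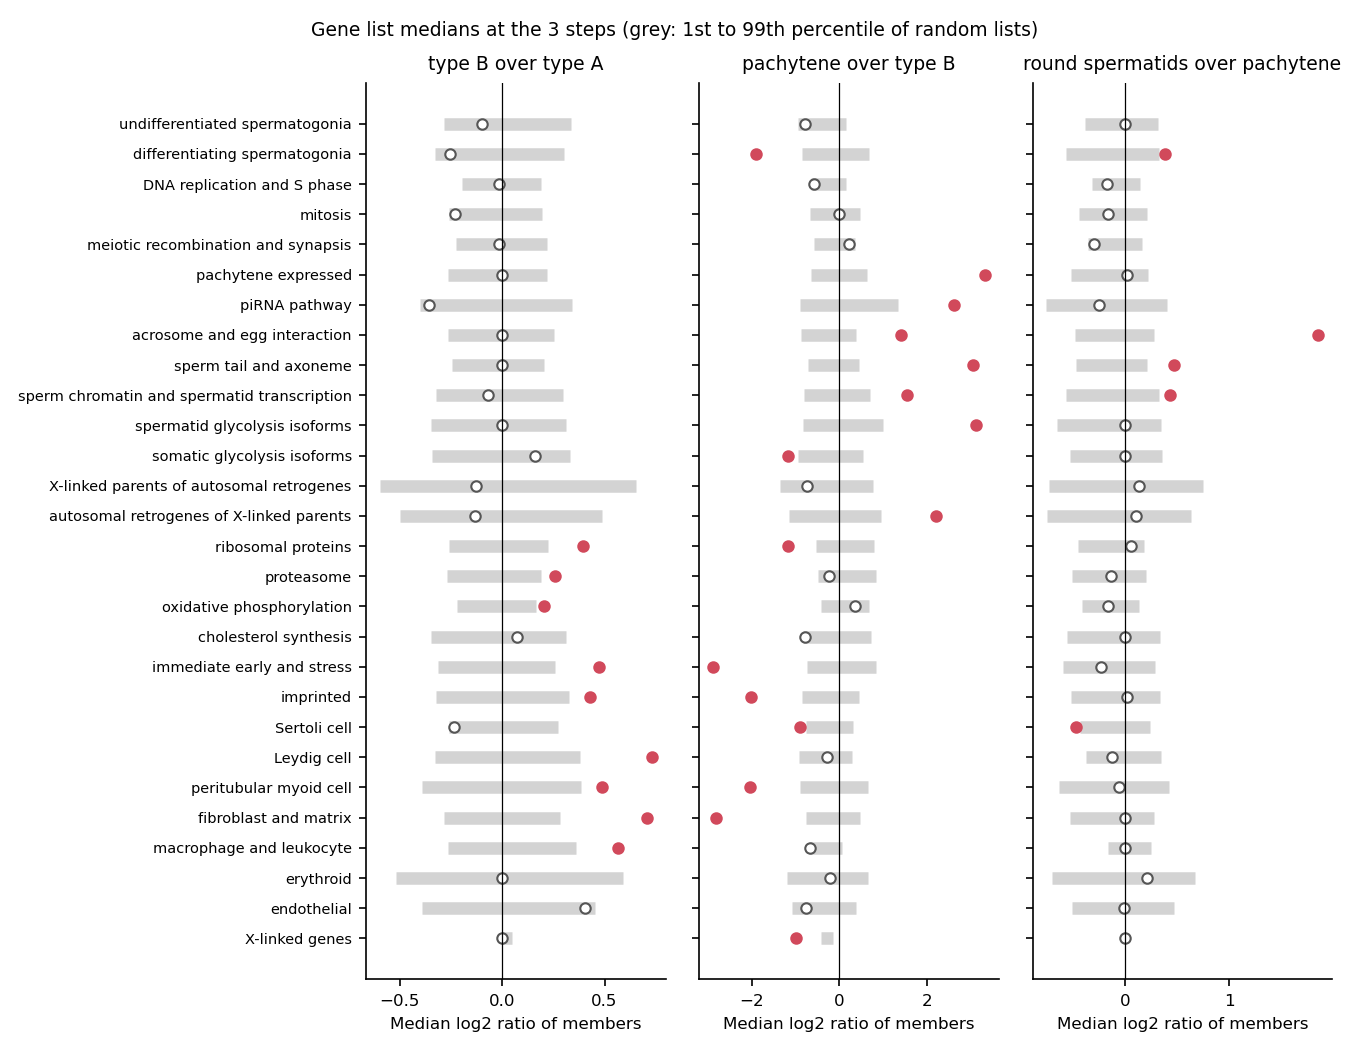
Median log2 ratio of each gene list at the 3 steps, filled where it lay outside the grey range from percentile 1 to percentile 99 of 10000 level-matched random lists. For type B over type A the filled medians are all positive, and all of them turned negative or to 0.00 under spike-in scaling.

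X-linked genes differed from autosomal genes between type B spermatogonia and pachytene spermatocytes. Silencing of the X and Y chromosomes is known in pachytene spermatocytes. Of 394 measured X-linked genes 196 were at least 2-fold lower in pachytene spermatocytes than in type B spermatogonia and 4 at least 2-fold higher. The ribosomal protein gene Rps4x was 17.2-fold, Itm2a at least 16.1-fold and Rhox13 11.8-fold lower, and Tsga8 was at least 9.95-fold higher. The median log2 of the X-linked genes was -0.99, against medians between -0.29 and -0.08 on the 19 autosomes, and 49.7% of X-linked genes were at least 2-fold lower against 18.4% to 23.7% of genes per autosome. The X-linked median lay at percentile 0 of matched random lists and outside the percentile limit in all 12 alternative settings, with -0.42 under spike-in scaling. By design, the X-linked median lay below the autosomal median by a log2 difference of -1.04 on U74Av2, -0.76 on U74Bv2 and -0.25 on U74Cv2. In type B over type A the X-linked median was 0.00, and it stood apart in 3 of 12 alternative settings, with -0.75 at percentile 0.2 under spike-in scaling. In round spermatids over pachytene it was also 0.00, and 0.24 at percentile 100 with no floor. At this step 62 X-linked genes were at least 2-fold higher and 21 lower, or 15.7% higher against 6.80% to 12.3% per autosome and 5.33% lower against 8.94% to 14.5%. Those higher included Tsga8 at 35.1-fold, Akap4, a main protein of the fibrous sheath, at 28.9-fold, Ctag2, from a signal under the highest negative control, at 16.4-fold and Ppp1r2-ps7 at least at 16.2-fold.

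**Figure D3:**
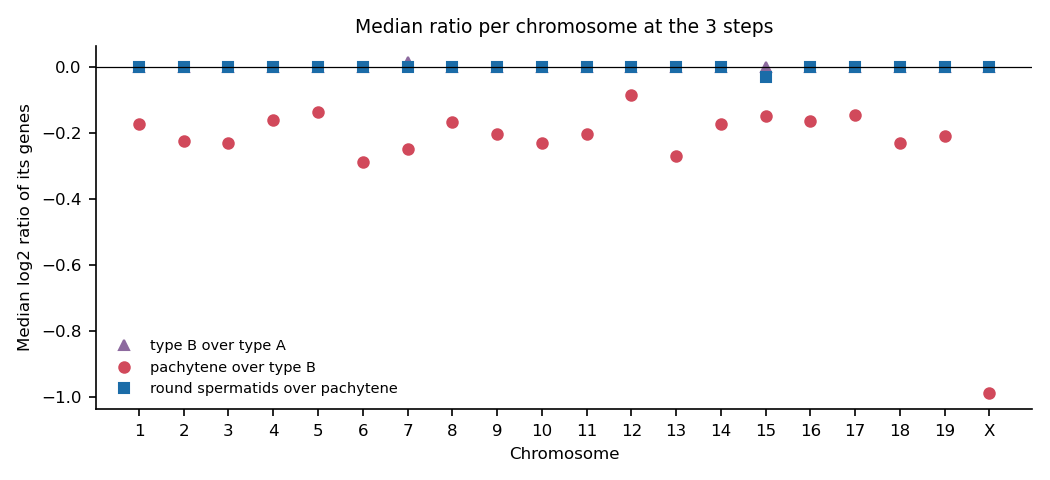
Median log2 ratio of the measured genes of each chromosome at the 3 steps. The X chromosome lay at -0.99 for pachytene over type B, below the autosomal range of -0.29 to -0.08, and at 0.00 at the other steps in the main setting. It came to -0.75 for type B over type A under spike-in scaling and to 0.24 for round spermatids over pachytene with no floor.

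The third comparison, of round spermatids with pachytene spermatocytes, covered the passage through the meiotic divisions to haploid cells, and 499 genes were at least 4-fold higher and 255 at least 4-fold lower in round spermatids. At a 2-fold threshold the split turned, with 1180 higher and 1537 lower. Acrosome and egg interaction genes led the higher lists: 15 of 26 were at least 2-fold higher and 1 lower, with a median log2 of 1.86, and the testis-specific kinase gene Tssk3 was at least 68.7-fold, its relative Tssk2 23.7-fold, Actl7a 26.1-fold and Zp3r 25.4-fold higher. Of 34 tail genes 12 were at least 2-fold higher and 5 lower, with a median of 0.47; Ropn1 was 33.7-fold, Akap4 28.9-fold, Smcp, of the mitochondrial capsule, 19.2-fold and the outer dense fibre gene Odf1 16.9-fold higher. Of 19 sperm chromatin genes 7 were at least 2-fold higher and 2 lower, with a median of 0.43; Kif17 was at least 34.4-fold, the linker histone gene H1f7 at least 31.8-fold, Prm3 24.2-fold and the transition protein gene Tnp2 21.2-fold higher. This last list passed the percentile limit in 9 of 12 alternative settings, and the other 2 in all 12.

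Between pachytene spermatocytes and round spermatids, the pachytene list had a median log2 of 0.02 that turned to -0.22 under spike-in scaling and to -0.10 under quantile normalization, with Calr3 at least 20.6-fold and Pgk2 7.52-fold higher and Spag1 6.08-fold and the transcription factor gene Mybl1 5.67-fold lower. In the piRNA pathway 5 of 13 genes were at least 2-fold lower in round spermatids and none higher, among them Rnf17 at least 9.70-fold, Piwil2 8.80-fold and Tdrkh 4.50-fold; the median of -0.26 did not stand apart. The germ cell metabolic list had a median of 0.00, with Aldoart2 14.2-fold and Gapdhs 13.2-fold higher and Slc2a3 4.86-fold lower. The recombination list had a median of -0.30 at percentile 2.19 that passed the limit in 2 of 12 alternative settings and turned to 0.14 on U74Av2 only, with 3 of 30 members at least 2-fold higher and 6 lower; Syce2 was 9.91-fold and the meiotic cohesin gene Rec8 4.31-fold higher, and the kinase gene Atr 3.85-fold and Terb1 3.69-fold lower, each under 2-fold with another treatment of its probe sets. Genes of differentiating spermatogonia had a median of 0.38 that stood apart, as it did in 11 of 12 alternative settings, with 5 of 19 at least 2-fold higher and 2 lower, such as Fthl17a 4.58-fold, Dazl 2.71-fold and Rhox13 2.66-fold higher and Rbm44 9.32-fold lower. The bootstrap interval of this median over genes ran from 0 to 0.83, and 4 of the 19, Rhox13 among them, are X-linked. Of 25 Sertoli cell genes 10 were at least 2-fold lower and none higher, with a median of -0.47 that stood apart, as it did in 10 of 12 alternative settings; Clu, clusterin, was 8.02-fold and Ctsl 6.67-fold lower. In the Leydig list, with a median of -0.13 that stood apart in 2 of 12 alternative settings only, Cyp17a1 was at least 7.33-fold lower.

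The largest ratios in round spermatids over pachytene spermatocytes among genes measured in both were those of the homeobox gene Nkx2-6 at 57.7-fold, Iqcf3 at 48.1-fold, 1700019M22Rik at 48.0-fold and Trim36 at 42.5-fold. They were followed by Cdrt4 at 39.0-fold, Klhl10, an adaptor of a ubiquitin ligase in spermatids, at 39.0-fold, Sun5, of the junction of sperm head and tail, at 37.7-fold and Cct8l1 at 37.6-fold. The pachytene signals of Nkx2-6 and Cct8l1 lay under the highest negative control of that array, as did the lower signal of 15 of 350 higher and 5 of 187 lower genes measured in both. From the floor, the phosphatase gene Dusp13 was at least 83.0-fold, Fam183b at least 48.4-fold, the deubiquitinase gene Otub2 at least 48.2-fold and 1700034E13Rik at least 47.0-fold higher. The lower genes were led by 4930579G24Rik at 20.5-fold, Baz1a, a chromatin remodelling subunit, at 16.02-fold, the ceramide synthase gene Cers3 at 15.8-fold, Kctd7 at 15.6-fold, Lcorl at 14.5-fold, Tmem185b at 12.7-fold, Gmcl1 at 12.5-fold and Tmem184a at 11.9-fold. Also lower were 1700040D17Rik at least 45.3-fold, Tmem255a at least 14.3-fold, Gm6653 at least 13.9-fold and Cdc42ep4 at least 9.54-fold. The spread of the control probe sets was the highest of the 3 steps here in the main setting. It was the lowest of the 3 with no floor, and it became smaller under spike-in scaling. Other probe sets differed by at least 2-fold in the same direction in 51 of 160 higher and 48 of 127 lower genes that had them.

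Over all 4 cell types, 383 genes peaked in round spermatids, at a level at least 4-fold over each of the other 3, against 79 in pachytene spermatocytes, 8 in type B spermatogonia and 5 in type A spermatogonia. Under spike-in scaling 1 gene peaked in type B and 56 in type A spermatogonia. The peaks in round spermatids were led by Dusp13, Tssk3, Nkx2-6, Fam183b and Otub2. Those in pachytene spermatocytes were led by 1700040D17Rik at 30.6-fold over the next cell type, Cers3 at 15.8-fold, 4930524B15Rik at 10.2-fold, Rnf17 at least at 9.70-fold and Tcam1 at 9.52-fold. Sgip1 peaked in type B spermatogonia at 8.49-fold, followed by Gpr75, Gm10125, Lyz1 and Itm2a, and Irf2bpl peaked in type A spermatogonia at 10-fold, followed by Agps, Rab27b, Lrrc75b at 4.03-fold and Mob3b at 4.01-fold. The signals of Irf2bpl, Agps and Mob3b in type B spermatogonia lay under the highest negative control. The ratio of Mob3b to type B spermatogonia turned when another probe set was taken. Of the genes higher at pachytene, 603 stayed within 2-fold in round spermatids, 101 were at least 4-fold lower there and 47 were at least 4-fold higher again. Of the genes lower at pachytene, 549 stayed within 2-fold and 19 were at least 4-fold higher in round spermatids.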

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

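The tests of the repeat signals below were chosen after the signals were seen.

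Control probe sets for mouse repeat RNA, which enter no gene comparison, read over the highest negative control of 103.5 signal units on all 12 arrays. The lowest signal of the B1 repeat probe set was 505, that of the B2 probe set 8165 and that of a second B2 probe set 307. Of the 6846 probe sets without a gene symbol 2256, and of the 724 with several gene symbols 389, also read over the highest negative control on at least 1 array. Among those without a symbol and over the floor, 36 were at least 4-fold higher and 23 lower in type B over type A, 75 higher and 104 lower in pachytene over type B, and 30 higher and 23 lower in round spermatids over pachytene. Among those with several symbols, 2 were higher and 0 lower, 32 higher and 35 lower, and 20 higher and 6 lower at the same steps.

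The B1 signal was 3.02-fold lower in pachytene spermatocytes than in type B spermatogonia and 13.9-fold lower in round spermatids. Noise of the probe set as the cause is argued against by its log2 ratio of round spermatids over type B, -3.80 with an SD of 0.23 over the 3 designs. Scaling of the arrays as the whole cause is argued against by the B2 probe set on the same arrays. Against it B1 was lower by a further log2 difference of -2.85, with an SD of 0.09 over the 3 designs. These SDs are technical, since the designs are no separate samples of a cell type. That B2 probe set gave the highest signal of the type B U74Cv2 array and may be saturated there, but against the second B2 probe set, whose signals reached only 3260, the difference was -2.78 (SD 0.17). A difference in B1 transcription between the cell types, which the design names, and a difference in how much B1 sequence other transcripts carry stay open and were not tested.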

How the results depend on the processing

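The tests with spike-in scaling and with the probe set chosen on a common scale of the designs were chosen after seeing the data. No paired analysis was possible because each cell type had 1 array per design and no test was run; for the same reason no array could be left out. Signals as deposited gave the same counts, and no list median left its bootstrap interval there or with the common scale of the designs. For the alternatives 2000 random lists were drawn, and between 27 and 33 of 84 combinations of list and step stood apart, against 30 in the main setting; on U74Av2 only, the piRNA list had too few genes for a value. Of 1005 list medians under alternatives 934 stayed within their bootstrap interval, among them 84 that are the same by construction since only the random lists were unmatched, while 63 moved and 8 reversed. Medians from signals as deposited nearly repeat the main setting. Some intervals are wide, such as -0.38 to 3.28 for the piRNA list in pachytene over type B. Staying within such an interval says little of robustness. Reversal was counted only for lists that stood apart or had a median of at least 1 in size on the log2 scale. Signal over background limits the counts, since negative controls read up to 103.5: lower genes in pachytene over type B numbered 1056 with the floor at 0.2 and 327 with the floor at 0.8. Counts under U74Av2 only cover fewer genes, and other fold thresholds and floors act by construction; for all other shifts the cause was not tested.

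Counts at least 4-fold higher and lower in type B over type A, 20 and 21 in the main setting, moved to 9 higher under a common median, 34 lower under quantile normalization, 65 and 62 with the floor at 0.2, 6 and 7 with the floor at 0.8, 218 and 168 with no floor, and 12 and 11 with the mean over probe sets. They moved to 11 and 12 without special endings, 5 and 0 on U74Av2 only, 71 and 63 with each probe set on its own, 468 and 471 at 2-fold, 1 and 3 at 8-fold, and 1 and 172 under spike-in scaling. The share of higher genes was 48.8% in the main setting, 26.5% under a common median (9 and 25) and 0.578% under spike-in scaling. For pachytene over type B, 970 and 668, they moved to 339 lower under a common median, 1056 lower with the floor at 0.2, 327 lower with the floor at 0.8, and 1478 lower with no floor. They moved to 437 lower with the mean over probe sets, 331 and 347 on U74Av2 only, 2105 and 2854 at 2-fold, 479 and 138 at 8-fold, and 1543 and 242 under spike-in scaling. The share of higher genes was 59.2%, against 80.7% under a common median, 86.4% under spike-in scaling, 45.5% with no floor, 48.8% on U74Av2 only and 42.4% at 2-fold. For round spermatids over pachytene, 499 and 255, they moved to 383 lower with the floor at 0.2, 149 lower with the floor at 0.8, and 843 and 604 with no floor. They moved to 159 lower with the mean over probe sets, 140 and 78 on U74Av2 only, 392 lower with each probe set on its own, 1180 and 1537 at 2-fold, and 263 and 38 at 8-fold, the share of higher genes being 66.2% in the main setting and 43.4% at 2-fold. Of the genes called in the main setting, 970 of 970 higher and 242 of 668 lower genes in pachytene over type B, and 1 of 20 higher and 21 of 21 lower in type B over type A, were kept under spike-in scaling.

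Peak counts in type A, type B, pachytene and round spermatids, 5, 8, 79 and 383, moved to 10 in type A under quantile normalization, 4 in type B under a common median, 15 and 14 in type A and type B with the floor at 0.2, 1 and 3 with the floor at 0.8, 35 and 31 with no floor, and 2 and 5 with the mean over probe sets. They moved to 56 and 1 in these types under spike-in scaling, 30, 31 and 122 in the first 3 types with each probe set on its own, 0, 3, 15 and 97 on U74Av2 only, 228, 180, 484 and 756 at 2-fold, and 1, 1, 8 and 224 at 8-fold.

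The Spearman correlation across genes of type A with pachytene, type A with round spermatids, type B with pachytene and type B with round spermatids moved to 0.638, 0.518, 0.628 and 0.536 with the floor at 0.2 and to 0.434, 0.279, 0.424 and 0.308 with the floor at 0.8. There the correlation of pachytene with round spermatids moved to 0.738. Type A and type B with pachytene moved to 0.533 and 0.525 with the mean over probe sets and to 0.539 and 0.529 without special endings. On U74Av2 only, type A with round spermatids gave 0.455, type B with pachytene 0.571 and type B with round spermatids 0.485, and under spike-in scaling type A with round spermatids gave 0.396. The SD of control probe sets at the 3 steps was 0.77, 0.75 and 0.73 with no floor, 0.32 for pachytene over type B under quantile normalization and 0.22 for round spermatids over pachytene under spike-in scaling.

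Spike-in scaling reversed in type B over type A the medians of ribosomal (-0.41), proteasome (-0.56), respiratory chain (-0.59), immediate early (-0.35), imprinted (-0.25), Leydig (-0.019), myoid (-0.37) and fibroblast genes (-0.11). There it also moved undifferentiated (-0.89), differentiating (-1.09), replication (-0.84), mitosis (-1.05), recombination (-0.81), pachytene (-0.56), piRNA (-1.08), sperm chromatin (-0.53), germ cell metabolic (-0.023), general metabolic (-0.40), X-linked parent (-0.81), retrogene (-0.60), sterol (-0.75), Sertoli (-0.97), macrophage (0.00), endothelial (-0.45) and X-linked genes (-0.75). For pachytene over type B it moved undifferentiated (-0.028), replication (0.00), mitosis (0.98), X-linked parent (-0.20), ribosomal (-0.40), proteasome (0.51), respiratory chain (1.10), immediate early (-2.13), Sertoli (-0.14), Leydig (0.22), macrophage (-0.13), endothelial (-0.15) and X-linked genes (-0.42), and for round spermatids over pachytene the pachytene list (-0.22). The acrosome, tail and germ cell metabolic lists stood apart in type B over type A under this scaling, as did the X-linked parents in pachytene over type B with no floor.

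Under a common median, medians for pachytene over type B moved for replication (-0.13), respiratory chain (0.87), immediate early (-2.37), Leydig (0.00), endothelial (-0.37) and X-linked genes (-0.57), and respiratory chain genes came to 0.051 in type B over type A. Quantile normalization moved for pachytene over type B the respiratory chain (0.13), Leydig (-0.10) and X-linked genes (-0.82). U74Av2 only moved undifferentiated (-0.072) and X-linked genes (-1.17) at that step and recombination genes (0.14) in round spermatids over pachytene. The floor at 0.2 moved acrosome (0.066) and macrophage genes (0.72) in type B over type A, X-linked genes (-1.18) in pachytene over type B, and X-linked parents (0.45) and sterol genes (-0.25) in round spermatids over pachytene; the floor at 0.8 moved X-linked genes to -0.67 in pachytene over type B. Without a floor, medians moved for acrosome (0.50), tail (0.32) and macrophage genes (0.86) in type B over type A, tail (4.19), X-linked parent (-2.57), macrophage (-1.33) and X-linked genes (-1.49) in pachytene over type B. For round spermatids over pachytene they moved for X-linked parent (1.12), Sertoli (-1.51), Leydig (-1.57), fibroblast (0.33), macrophage (0.25) and X-linked genes (0.24).

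Of the single genes named, the direction in type B over type A reversed for Kcnma1 (0.034) and Pdlim7 (0.22 and 0.48) without special endings, on U74Av2 only and on a common scale, and for Utf1 (-0.43) in the same 3 settings. It also reversed for Sall4 without special endings (-2.05), on U74Av2 only (-1.15) and with the mean over probe sets (-0.60), for Sh2d3c (-0.74) without special endings and on a common scale, for Gfra1 (0.048) on U74Av2 only and for Mob3b (0.17) on a common scale. In pachytene over type B, Prps1l1 came to -0.036 without special endings. Some named genes under 2-fold in the main setting turned as well. At that step these were Rbmx (up to 0.55) and Clu (up to 0.42), each in 2 of 11 alternative settings. For type B over type A they were Col1a1 (-0.04) and Cyp17a1 (-0.06), each in 1 of 11.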

Other observations

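The tests below of scaling, of the share of germ cells, of interstitial cells and of RNA of other cells were chosen after the results were seen.

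Of 16 imprinted genes 10 were at least 2-fold lower in pachytene spermatocytes than in type B spermatogonia and none higher, with a median log2 of -2.02 that stood apart. Matrix and myoid genes, markers of other cell types, were lower alike on these arrays, with medians of -2.80 and -2.03. Besides Dlk1, and Plagl1 in part of the settings, Igf2, a fetal growth factor, was 15.2-fold, Ndn at least 12.2-fold and Peg3 at least 11.4-fold lower. None of the lists below stood apart at the step given in the main setting. The proteasome list had a median of -0.23 at this step, which turned to 0.26 under a common median and to 0.51 under spike-in scaling. Its members parted: Psma8, a germ cell form of an alpha subunit, was 7.25-fold higher at pachytene and 3.89-fold lower in round spermatids, and Psma7 was 4.54-fold lower at pachytene. Respiratory chain genes had a median of 0.36 at pachytene, with 7 of 40 at least 2-fold higher and 2 lower, among them Ndufb10 at 2.82-fold higher and the X-linked Cox7b at least 4.84-fold lower. Sterol synthesis genes had a median of -0.79 at percentile 1.66, with Insig1 at least 4.37-fold and Hmgcs1 3.49-fold lower. The erythroid list had a median of 0.00 in type B over type A, where Hba-a1 was 2.81-fold higher, or by a log2 of 0.67 under spike-in scaling.

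Some genes were low in pachytene spermatocytes alone. For Sall4 this rests on the choice of probe set, since its log2 ratio of round spermatids over pachytene came to 0.00 on U74Av2 only and without special endings, and to 0.87 with the mean over probe sets. The signal of Syce2 was 292 in type B spermatogonia, 57.4 in pachytene spermatocytes and 569 in round spermatids, that of Sall4 647, 96.8 and 588, and that of the transcription factor gene Klf4 1209, 133 and 1165. The Y-linked genes Eif2s3y, Kdm5d and Uba1y had signals of 174, 109 and 188 in type B spermatogonia and lay under the floor in pachytene spermatocytes, at least 3.49-fold, 2.18-fold and 3.75-fold lower, with Kdm5d under 2-fold in 5 of the 9 alternative settings that gave it a value. In round spermatids Eif2s3y read 194, Uba1y 82.6 and Kdm5d under the floor. Sry reached 52.5 in pachytene spermatocytes and lay under the floor elsewhere. The Leydig cell gene Cyp17a1 read 150.02 in type A, 254 in type B, 366 in pachytene and under the floor in round spermatids. Its direction from type A to type B turned in 1 of 11 alternative settings, to a log2 of -0.06.

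Relative to other genes, genes of interstitial cells were higher on the type B than on the type A arrays, while the Sertoli median of -0.24 did not stand apart. Col1a1 read 2054 against 1192 signal units, a difference that turned in 1 of 11 alternative settings, to a log2 of -0.04. The lowest percentile of the fibroblast list under the 4 other scalings was 100. Apart from quantile normalization, 1 factor per array moves the list and its random lists nearly alike, so this hardly tests scaling as a cause. Signals as deposited nearly repeat the main setting. The fibroblast median turned to -0.11 under spike-in scaling. There the myoid and macrophage lists no longer stood apart, and scaling stays open for them. A lower share of germ cells, raising all other types alike, would raise the Sertoli list too. The fibroblast median exceeded the Sertoli median by 0.94 on the log2 scale (95% bootstrap interval over genes 0.54 to 1.41). This difference is part of the pattern that prompted the test, so it is no separate evidence against that explanation. More interstitial cells among the cells taken as type B may be a source. The endothelial list, with a median of 0.41, had an interval from -0.04 to 0.82, and from 0.04 to 0.82 in another bootstrap run. Whether the interval held 0 depended on the draw, so the list left this open. More interstitial cells cannot be told apart from expression of these genes in the germ cells themselves. A first test of the same explanation, whether the medians of the 4 interstitial lists lay over 0, was dropped after its result had been seen because it repeated the pattern: the lower ends of their intervals were 0.25, 0.16, 0.46 and 0.17.

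X-linked genes were lower than autosomal genes in pachytene spermatocytes against type B spermatogonia. The log2 difference between the X-linked and autosomal medians came no nearer to 0 than -0.66 under the 4 other scalings. Apart from quantile normalization, these apply at most 1 factor per array, which moves X-linked and autosomal genes alike except at the floor. Their outcome was thus nearly fixed, and they do not test scaling as a cause. With quantile normalization, which is not bound in this way, the difference was -0.80. The floor as the whole cause is argued against by the 189 X-linked and 8848 autosomal genes over it in both cell types. Their difference was -0.88 (95% bootstrap interval over genes -1.06 to -0.80). That interval leaves out differences between arrays. By design, the difference over all measured genes ran from -1.04 on U74Av2 to -0.25 on U74Cv2. Loss of RNA of other cells may contribute and cannot be told apart. In a test of it, 9 X-linked members of lists of general cell functions were set against the lists' autosomal members. They differed by a median of -0.77, with an interval from -1.13 to 0.33. Among them were Pola1 of replication and Kif4 of mitosis, which not every cell type uses. That test replaced a first one, also undecided, on 4 X-linked genes of differentiating spermatogonia (median -2.75, interval -3.57 to 0.17), and silencing of the X chromosome stays a hypothesis beside it.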
